A study of Homo sapiens with 6 samples.

How the data were processed

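RNA was sequenced from 6 samples of LX-2, an immortalised line of human hepatic stellate cells, the cells that make scar matrix in injured liver. Per the labels' protocols, cells were transfected with 50 nM of an siRNA against AEBP1 or of a scrambled siRNA by a lipid reagent, and RNA was taken after 48 hours. Libraries were made from 1 μg of total RNA with an mRNA library kit. There were 3 libraries per group. Whether the libraries came from separate transfections is not given in the sources used here, so p-values measure the spread between these samples, which may be technical.

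The authors deposited a table with raw counts and FPKM (fragments per kilobase of transcript and library size) per gene, per the file headers. The genome build was hg19, per the submitters' processing notes. The aligner, the counting program, the annotation, the strand setting and any filters are not given in the sources used here. Tests were run on the deposited counts, and the deposited FPKM values served as an alternative and as a second unit for AEBP1. The table held 24789 rows with values, of which 19974 carried an Ensembl gene ID and 4815 were loci the authors had assembled outside the annotation. A further 17 lines held fragments of annotation text with no values and were left out. A spreadsheet had turned 27 gene symbols into dates, and these were restored by gene ID. Of the Ensembl IDs, 19883 were in the reference name table.

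The total counts were 41330380, 49432960 and 43626594 in the libraries labelled scrambled 1, 2 and 3, and 34433510, 37553780 and 41600600 in those labelled AEBP1 siRNA 1, 2 and 3. Assembled loci took between 1.51% and 1.83% of counts. The counts of every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 7.84. No library was thus a copy of another, and all 6 were counted as separate libraries. Such a difference cannot show that the libraries came from separate cultures. Floors of 3 counts cover counting error only, since whether PCR copies were marked is not given in the sources used here.

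Groups were taken from the labels, and all levels are given for libraries as labelled. Genes were filtered with filterByExpr and scaled by trimmed mean of M values, which left 16250 genes. The groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment over all genes tested, and genes with an adjusted p under 0.05 were called. A gene's standard error was its log2 fold change divided by the square root of its F statistic. Single values were compared with exact two-sided permutation tests, which cannot go below p = 0.1 with 3 against 3. Gene lists, 27 in number with 747 members, were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01. The medians of lists are over log2 fold changes of the members tested. CPM values are counts divided by the scaled library size, times 1000000.

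The design, the gene lists, the rule for named genes and all but 4 of the alternatives were fixed before the data were examined. The rule named AEBP1, and 7 markers of stellate cell activation whatever their values. It also named up to 10 genes with the largest rise and 10 with the largest fall. These needed an adjusted p under 0.05, a mean of at least 5 CPM, a gene symbol and no overlap between groups. Up to 3 called members per list were named as well, or up to 4 in a list with 10 or more. Only SENP3-EIF4A1 met the rule for changed genes, and no list had a called member. Other genes were named after their values were seen. Examples beside a list test are among the 2 members of that list with the smallest unadjusted p, except that for markers of other cell types the member with the highest mean was named.

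The alternatives were a replicate block, each library left out, DESeq2 size factors, upper quartile scaling, no filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, an adjusted p under 0.01, a test against a fold of 1.5, camera with an estimated correlation, and fry. After the data were seen, 4 more were added, which left out replicate 3 of both groups, left out these and AEBP1 siRNA 1, left out assembled loci, or used limma on log2(FPKM + 1).

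The gene test was tested on simulated counts for the 16250 genes of this comparison. Changes were planted only in genes with a mean of at least 5 CPM, with the labels taken as correct. The test recovered 29.9% of 67 genes changed by 1.5-fold, 86.6% of 67 changed by 2-fold and 100% of 66 changed by 4-fold, and called 13 unchanged genes. Genes below that mean, such as ACTA2 and COL1A2, are not covered. Camera recovered a simulated log2 shift of 0.5 in the collagens and called 0 other lists. The simulated genes varied independently, while the lists called in the real data had estimated inter-gene correlations of 0.275 to 0.946. The simulation therefore cannot show how often camera calls such lists falsely. The shares recovered by the gene test rest on the same independence, with no structure of the samples besides the labels. The power in the real data is therefore not known.

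For the closing section, 3′ UTR heptamers were scanned with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The longest 3′ UTR of each gene came from GENCODE release 29, which is on GRCh38. It was used for sequence only, and the authors' build is another one. The scan took 10970 genes with a mean of at least 5 CPM and a 3′ UTR of at least 30 nt, which is 99.1% of annotated genes at that level. Differences in log2(CPM + 0.5) were adjusted for UTR length, GC content and mean level, their outer 1% on each side was trimmed to that limit, and genes with a heptamer were compared with genes without it for the 16192 heptamers present in, and absent from, at least 50 genes. Heptamers were ranked by effect divided by SE. In simulated data a planted effect of -0.1 was found at -0.0962, at rank 1. Standard errors of heptamer effects are across genes, which are not independent replicates.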

Results

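Gene expression was measured by RNA sequencing in LX-2 cells given an siRNA against AEBP1 or a scrambled siRNA, each at 50 nM for 48 hours. LX-2 is an established line of human hepatic stellate cells. AEBP1 encodes a collagen-binding matrix protein whose shorter form has been described as a transcriptional repressor. There were 3 libraries per group, with total counts of 34433510 to 49432960 each, and between 18189 and 19028 genes or loci had at least 1 count. The 10 most abundant genes took 2.49% to 2.79% of counts and mitochondrial transcripts 1.21% to 1.36%. The comparison asks what an AEBP1 siRNA changes in the transcriptome of these cells.

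The level of AEBP1 (ENSG00000106624) did not follow the labels. It was 53.6 and 48.7 CPM (counts scaled to library size) in the libraries labelled scrambled 1 and 2, and 25.1 CPM in the library labelled scrambled 3. It was 29.7 and 27.7 CPM in the libraries labelled AEBP1 siRNA 1 and 2, and 48.3 CPM in the library labelled AEBP1 siRNA 3. The library labelled scrambled 3 was thus below all 3 labelled AEBP1 siRNA, and the library labelled AEBP1 siRNA 3 was close to scrambled 2. The deposited FPKM values were 12.3, 11.5 and 6.35 in the libraries labelled scrambled and 7.94, 6.98 and 11.7 in those labelled AEBP1 siRNA, the same order except that AEBP1 siRNA 3 was above scrambled 2. Group means were 42.5 CPM ± 15.2 (SD, n = 3) and 35.2 CPM ± 11.4 (SD, n = 3), an exact permutation p of 0.6. The log2 fold change was -0.27 (SE 0.305, 95% interval -0.97 to 0.43, edgeR adjusted p = 0.991). All directions given for the groups below rest on these labels, against which AEBP1 goes in 2 of the 6 libraries.

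**Figure D1:**
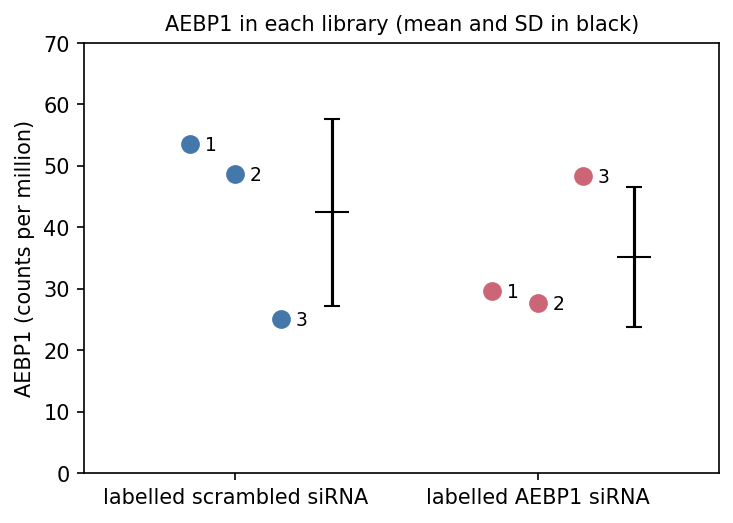
AEBP1 in CPM for each library, by labelled group, with the replicate number beside each point and the mean and SD of 3 libraries in black. The library labelled scrambled 3 sits at 25.1 and the library labelled AEBP1 siRNA 3 at 48.3.

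One annotated gene passed the threshold between the labelled groups. SENP3-EIF4A1 (ENSG00000277957), a read-through gene that spans the neighbouring SENP3 and EIF4A1, was higher in all 3 libraries labelled AEBP1 siRNA, at 232 CPM ± 89.9 (SD, n = 3) against 14.1 CPM ± 2.96 (SD, n = 3). Its log2 fold change was 4.03 (SE 0.296, edgeR adjusted p = 0.0105), and 0 genes were lower at that threshold. Both partner genes had lower values in the same libraries. SENP3, a SUMO protease, had 48.8 CPM ± 0.542 against 75.3 CPM ± 0.642, and EIF4A1, an RNA helicase of translation initiation, had 338 CPM ± 26.2 against 472 CPM ± 11.6. Their adjusted p-values were 0.225 and 0.991 by edgeR, and 1.46e-05 and 0.0454 by DESeq2, which called both. Summed over the 3 genes, the locus had 619 CPM ± 96.3 in the libraries labelled AEBP1 siRNA and 561 CPM ± 10.0 in those labelled scrambled, an exact permutation p of 0.5. The 3 genes overlap and can share reads, so the level of each is uncertain.

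**Figure D2:**
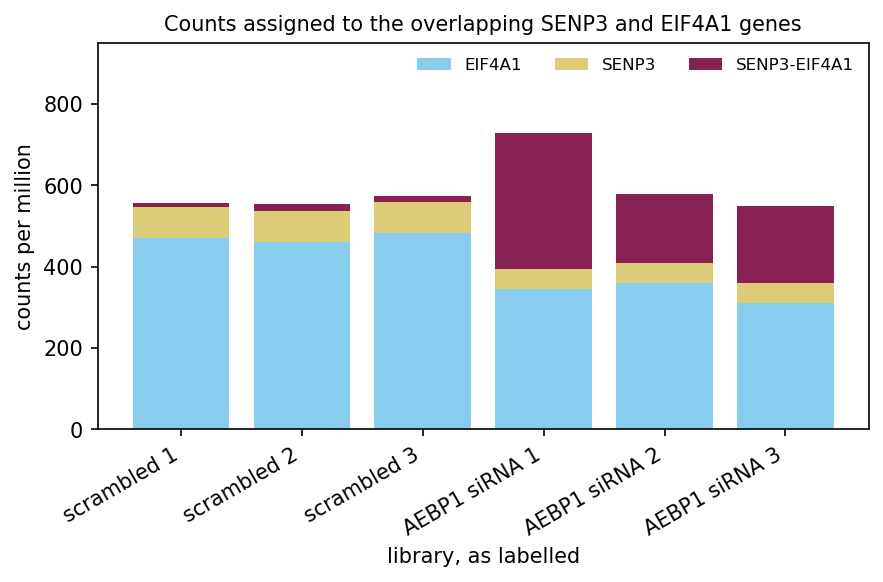
CPM assigned to EIF4A1, SENP3 and the read-through gene SENP3-EIF4A1, stacked for each library as labelled. The read-through part is 11.4 to 17.3 in the libraries labelled scrambled and 170 to 335 in those labelled AEBP1 siRNA, while the summed height is 554 to 573 and 550 to 729.

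Another pair of read-through genes followed the labelled groups without passing the threshold in edgeR, and were picked after their values were seen. RAB4B-EGLN2 had 0 counts in the 3 libraries labelled scrambled and 469, 165 and 429 counts in those labelled AEBP1 siRNA, at least 422-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.107). NEDD8-MDP1 had 41, 75 and 47 counts in the libraries labelled scrambled and 0 in each labelled AEBP1 siRNA, at least 45.4-fold lower against the same floor (edgeR adjusted p = 0.225). DESeq2 called both (adjusted p = 3.63e-15 and 1.46e-05), as did edgeR with no filter (0.00283 and 0.0406). RAB4B-EGLN2 was also called with a replicate block (0.0169) and without AEBP1 siRNA 2 (0.00859), and NEDD8-MDP1 by limma-voom (0.0202). Their partner genes RAB4B, EGLN2, NEDD8 and MDP1 had adjusted p-values of 0.991 by edgeR. Read-through genes were looked at as a class after 4 of them had been seen among the 10 genes with the smallest p. Of 65 tested, these 4 included, 9 (13.8%) had an unadjusted p under 0.05, as had 207 of 16185 other genes (1.28%).

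Of the 16250 genes tested, 216 had an unadjusted p under 0.05, 119 of them higher and 97 lower in the libraries labelled AEBP1 siRNA. That is a smaller share than the 0.05 that chance gives. DESeq2 called 6 genes, of which SENP3-EIF4A1 and RAB4B-EGLN2 were higher and NEDD8-MDP1, SENP3, EIF4A1 and an assembled locus lower. Limma-voom called 2, SENP3-EIF4A1 and NEDD8-MDP1. Labelled groups did not overlap for 963 genes, or 5.93%, where chance gives 10%. The call of SENP3-EIF4A1 was lost when a library labelled scrambled was left out, with adjusted p-values of 0.126, 0.0655 and 0.0929 without replicates 1, 2 and 3, while its log2 fold changes of 3.9, 4.21 and 4.01 were close to the 4.03 of all libraries.

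None of the 7 usual markers of stellate cell activation passed the threshold. ACTA2, the smooth muscle actin of myofibroblasts, was at 3.85 CPM ± 0.76 (SD, n = 3) in the libraries labelled scrambled and 4.19 CPM ± 1.35 in those labelled AEBP1 siRNA, a log2 fold change of 0.12. COL1A1, the main fibrillar collagen chain of scar, was the most abundant of the 7, at 1540 CPM ± 64.8 and 1480 CPM ± 81.7. Its log2 fold change was -0.057 with a 95% interval of -0.27 to 0.15. COL1A2, the other chain of type I collagen, was at 3.91 and 4.49 CPM, and COL3A1 was at 31.1 and 27.4 CPM. TIMP1, an inhibitor of matrix proteases, was at 135 and 140 CPM, and its log2 fold change was 0.052. TGFB1, the profibrotic cytokine, was at 78.9 and 89.1 CPM, and PDGFRB, a receptor for a stellate cell mitogen, at 34 and 32.5 CPM. The edgeR adjusted p was 0.991 for each of the 7. Without AEBP1 siRNA 1, the estimates of ACTA2, COL3A1, TIMP1 and PDGFRB changed sign, to -0.169, 0.0119, -0.0608 and 0.00902, and without scrambled 3 that of TIMP1 was -0.042.

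**Figure D3:**
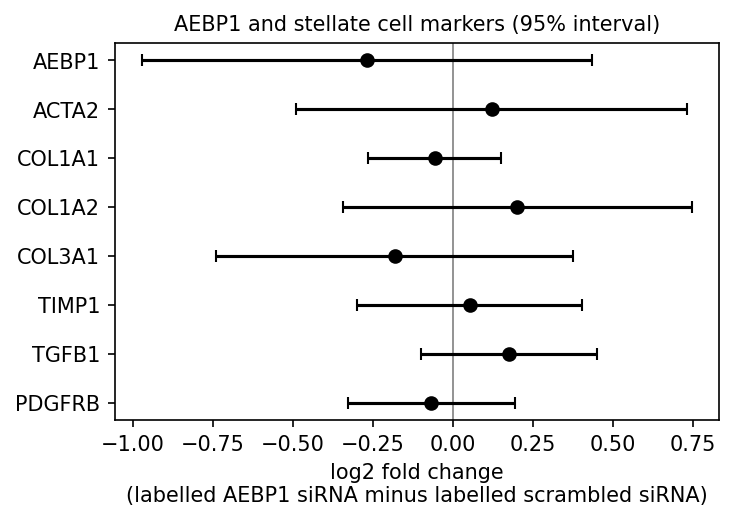
Log2 fold change of AEBP1 and 7 stellate cell markers, libraries labelled AEBP1 siRNA minus those labelled scrambled, with 95% intervals from the edgeR fit over 3 libraries per group. Every interval spans 0, and that of AEBP1 runs from -0.97 to 0.43.

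The matrix lists held few differences between the labelled groups. Matrix glycoproteins and proteoglycans had lower estimates for 21 of 27 members in the libraries labelled AEBP1 siRNA, with a median log2 fold change of -0.14, and were called by camera (adjusted p = 0.0216). With an estimated correlation the adjusted p was 0.93. Fibronectin (FN1), an abundant adhesive glycoprotein, was at 2530 and 2000 CPM in the libraries labelled scrambled and AEBP1 siRNA. Without AEBP1 siRNA 1 the list median was 0.00856, and the call was also lost without scrambled 2 (adjusted p = 0.18) or scrambled 3 (0.0948). Of 22 collagens tested, 17 had lower estimates, with a median of -0.084 (camera adjusted p = 0.224), and COL4A2 of basement membrane was at 916 and 835 CPM. The collagens were called as lower without AEBP1 siRNA 3 (adjusted p = 0.0216) and with a mean of at least 5 CPM (0.0493). Collagen processing and crosslinking genes, matrix proteases and their inhibitors, and integrins and adhesion receptors had medians of 0.027, -0.018 and -0.057, with camera adjusted p-values of 0.897, 0.928 and 0.224.

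Genes of the type I interferon response had lower estimates for 26 of 34 members in the libraries labelled AEBP1 siRNA, with a median log2 fold change of -0.18. Relative to the mean of the 6 libraries, list medians were 0.301, 0.107 and -0.138 in scrambled 1, 2 and 3. They were -0.115, -0.214 and 0.073 in AEBP1 siRNA 1, 2 and 3, so replicate 3 went the other way. Camera called the list (adjusted p = 0.000845), and with an estimated correlation the adjusted p was 0.93. OAS2 and OAS1, which make the activator of the antiviral ribonuclease RNase L, were at 25.9 and 12.5 CPM in the libraries labelled scrambled and 19.4 and 8.39 CPM in those labelled AEBP1 siRNA, with adjusted p-values of 0.991 by edgeR. The list was no longer called without scrambled 1, where its median was -0.0747 (adjusted p = 0.595), or without AEBP1 siRNA 2, where it was -0.148 (adjusted p = 0.3). Without scrambled 3 the median was -0.314 (adjusted p = 3.21e-08). NF-kB and inflammatory genes had a median of -0.047 over 36 members (camera adjusted p = 0.727), but were called as lower without scrambled 3 (adjusted p = 9.71e-05). Among them PTGS2, the inducible prostaglandin synthase, was at 7.79 and 5.32 CPM (edgeR adjusted p = 0.991).

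Cytosolic ribosomal proteins had higher estimates for 36 of 36 members in the libraries labelled AEBP1 siRNA, with a median of 0.14 (camera adjusted p = 2.24e-05). Nuclear genes of the respiratory chain had higher estimates for 26 of 30 members, with a median of 0.095 (camera adjusted p = 0.016). With an estimated correlation the adjusted p was 0.93 for both. RPL13 was at 258 and 317 CPM and NDUFA4 at 48.3 and 58.9 CPM in the libraries labelled scrambled and AEBP1 siRNA. Both medians changed sign without AEBP1 siRNA 1, to -0.0296 for ribosomal proteins (adjusted p = 0.556) and -0.0312 for the respiratory chain (adjusted p = 0.537). Without scrambled 3 neither was called, with adjusted p-values of 0.0799 and 0.466. The library labelled AEBP1 siRNA 1 stood apart from the other 5. Its first principal component score was 65.9, where the others lay between -17.3 and -5.74. Relative to the mean of the 6 libraries, its list medians were 0.358 for ribosomal proteins, 0.301 for the respiratory chain and -0.387 for matrix glycoproteins. On the second component, with 21.4% of the variance, scrambled 1 and 2 and AEBP1 siRNA 3 scored 30, 14.3 and 17.8. AEBP1 siRNA 1 scored -1.99, and scrambled 3 and AEBP1 siRNA 2 scored -26 and -34.1.

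**Figure D4:**
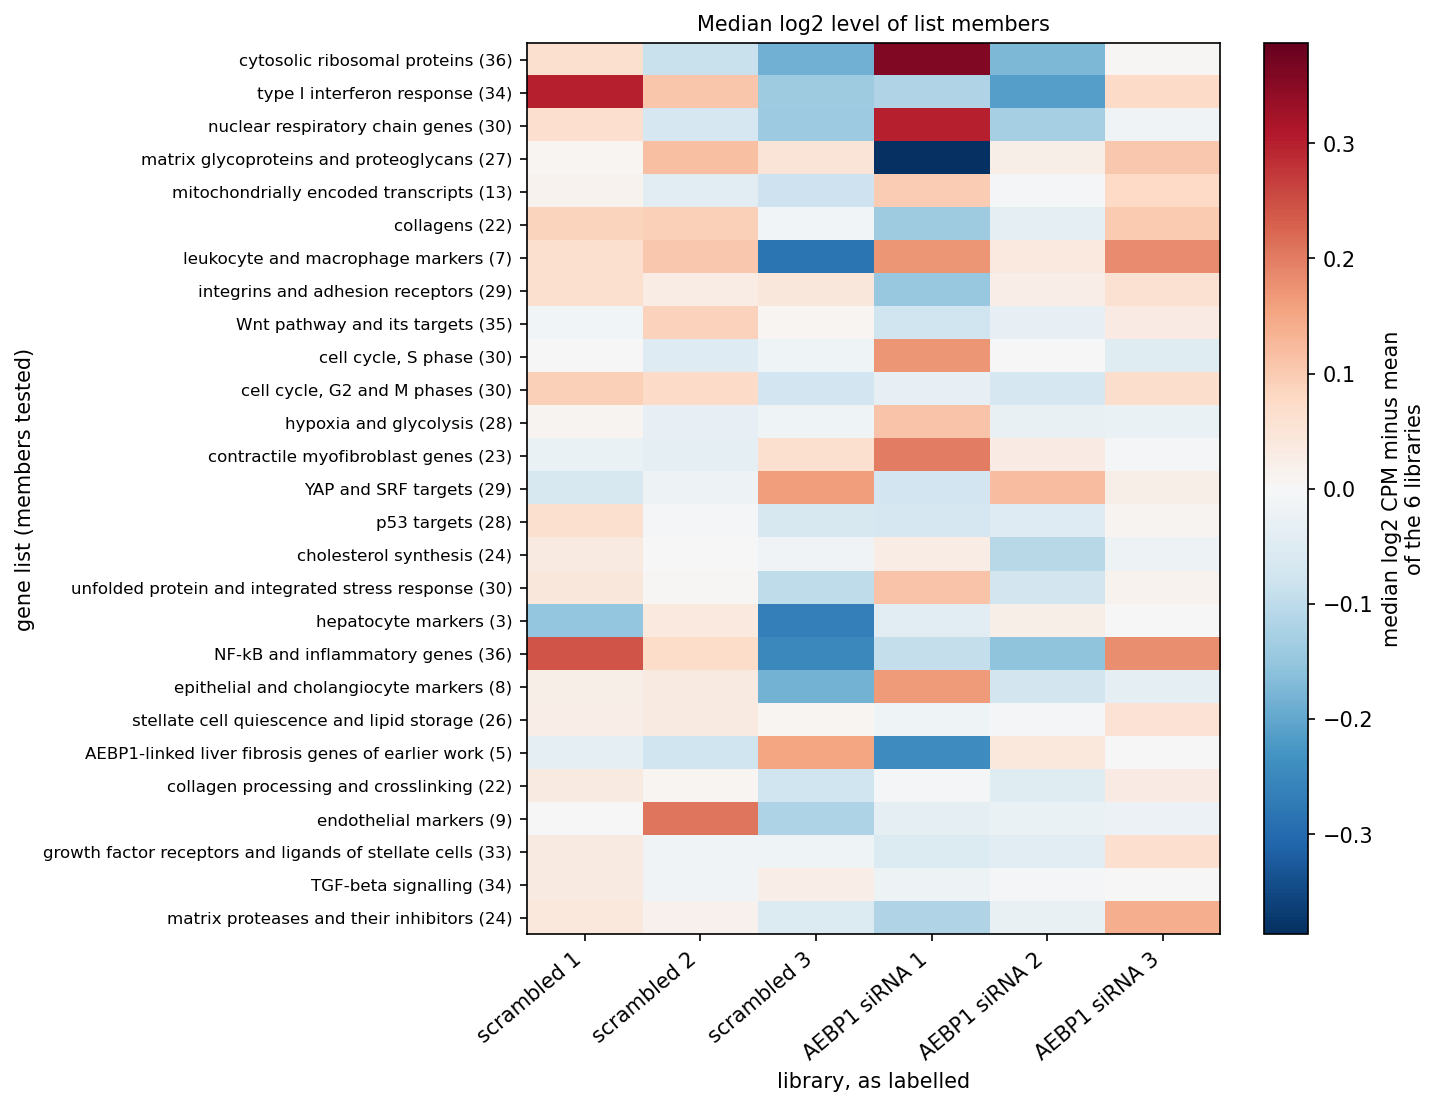
Median log2 level of the tested members of each gene list, relative to the mean of the 6 libraries, for each library as labelled. The library labelled AEBP1 siRNA 1 has the highest value for ribosomal proteins, at 0.358, and the lowest for matrix glycoproteins, at -0.387.

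Across all 27 lists, 0 members were called, and 0 were called when adjusted over the list alone. Camera called the 2 lists higher and 2 lower that are given above, of which 0 held with an estimated correlation, and fry called 0. The remaining lists had camera adjusted p-values of at least 0.102, the lowest being that of the mitochondrially encoded transcripts (median 0.094), which were called as higher without AEBP1 siRNA 1 (adjusted p = 0.00358) and with a mean of at least 5 CPM (0.0493). Genes of the S phase had a median of 0.046 and those of the G2 and M phases -0.038, called as lower without scrambled 3 (adjusted p = 0.0159). In the latter list TOP2A, the topoisomerase of dividing cells, was at 727 and 641 CPM. Contractile myofibroblast genes had a median of 0.079, and CNN1, the calponin of smooth muscle, was at 20.8 and 25.8 CPM. Stellate cell quiescence and lipid storage genes had a median of -0.022, and targets of YAP and SRF 0.033. The Wnt pathway had a median of -0.070, with its transcription factor LEF1 at 26.2 and 22 CPM. Medians were -0.047 for p53 targets, -0.0088 for cholesterol synthesis, 0.030 for the unfolded protein and integrated stress response, and 0.0046 for hypoxia and glycolysis. Those of TGF-beta signalling, of growth factor receptors and ligands of stellate cells, and of 5 genes linked to AEBP1 in earlier work on liver fibrosis were -0.032, -0.028 and -0.0089. Median, mean and camera direction differed in sign for 7 lists, namely those of collagen processing, matrix proteases, growth factor receptors, TGF-beta signalling, and hepatocyte, epithelial and endothelial markers.

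Markers of other liver cell types were low or did not differ between the labelled groups by camera. Of 20 hepatocyte markers 3 were tested, and the highest mean was that of SERPINA1 at 6.63 CPM. Of 18 epithelial and cholangiocyte markers 8 were tested, led by the keratin KRT18 at 167 CPM. Of 18 leukocyte and macrophage markers 7 were tested, led by CD68 at 20.6 CPM, and of 18 endothelial markers 9, led by FLT1 at 63.2 CPM. Their camera adjusted p-values were 0.727, 0.802, 0.224 and 0.928.

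With replicate 3 of both groups left out, a comparison chosen after AEBP1 had been seen, the AEBP1 log2 fold change was -0.835 (edgeR adjusted p = 0.378). One gene was called, AL355312.5, which was lower, and 765 had an unadjusted p under 0.05, of which 346 were higher and 419 lower in the libraries labelled AEBP1 siRNA 1 and 2. With AEBP1 siRNA 1 left out as well, 249 genes were called, 111 higher and 138 lower, and AEBP1 had a log2 fold change of -0.884 (edgeR adjusted p = 0.00536). That fit has a single library labelled AEBP1 siRNA, which is assumed to vary like the other group.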

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

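The settings that left out replicate 3 of both groups, left out these and AEBP1 siRNA 1, left out assembled loci, or used log2(FPKM + 1) were chosen after the data were seen. The log2 fold change of AEBP1 was below 0 under every alternative run, from -0.066 without scrambled 1 to -0.884 without replicate 3 of both groups and AEBP1 siRNA 1, where it passed the threshold with a single library on one side. Its adjusted p was at least 0.378 under the others. Against 1 gene called, and 1 changed at least 2-fold, no filter beyond a nonzero total gave 3 and 3, DESeq2 6 and 4, and limma-voom 2 and 2, while an adjusted p under 0.01 left 0 genes. The replicate numbers gave no sign of pairing. Deviations of same-numbered libraries from their labelled group means correlated at 0.0961, -0.00776 and -0.102, and not every library correlated best with its own number. The check rests on the labelled groups, so it cannot exclude pairing. The replicate block gave 2 genes, 2 of them at least 2-fold. Leaving out single libraries gave 0 to 2 genes, 0 to 2 at least 2-fold, and 2 to 5 gene lists against 4. A mean of at least 5 CPM gave 6 lists, with collagens and mitochondrially encoded transcripts added. Camera with an estimated correlation and fry called 0 lists.

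Without single libraries, the log2 fold changes ran from -0.169 to 0.294 for ACTA2, -0.412 to 0.0119 for COL3A1, -0.0608 to 0.181 for TIMP1 and -0.119 to 0.00902 for PDGFRB. List medians ran from -0.314 to -0.0747 for the type I interferon response, -0.0296 to 0.248 for ribosomal proteins, -0.0312 to 0.214 for the respiratory chain and -0.223 to 0.00856 for matrix glycoproteins. With replicate 3 of both groups left out, TIMP1 was at -0.0682. With AEBP1 siRNA 1 left out as well, 249 genes were called, 85 of them at least 2-fold, and 7 lists, with ACTA2 at -0.146, TIMP1 at -0.339, PDGFRB at 0.0543, ribosomal proteins at -0.167 and the respiratory chain at -0.149. For these reversals the cause was not tested. Among results that answer a comparison, 48 values under alternatives stayed on their side of the threshold and direction or within 1.5 times the main count. Of the rest, 21 counts moved, 1 value became stronger in the fit with a single library on one side, and 0 reversed. Counts could not be labelled as reversed, and a count that stayed can hold another gene, such as AC007192.1 without scrambled 3. Among named genes and lists, 167 values stayed, 21 became weaker and 14 reversed. Pseudocounts of normalized values were not run, since counts were tested. At 34433510 to 49432960 counts and 3 libraries per group, 29.9% of simulated changes of 1.5-fold, planted in genes with a mean of at least 5 CPM, were recovered. Those simulated genes varied independently, with no sample structure besides the labels, so the share in the real data is not known.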

Other observations

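Every test in this part was chosen after the results were seen, except those of length, GC content and depth in the library labelled AEBP1 siRNA 1. These were written before their values were known, though after that library was seen to stand apart. With replicate 3 of both groups left out, the genes with the smallest p included several of known function, none past the threshold. TPM4, an actin-binding tropomyosin, was at 313 and 281 CPM in the libraries labelled scrambled 1 and 2 and at 839 and 825 CPM in those labelled AEBP1 siRNA 1 and 2 (log2 fold change 1.48, SE 0.133, edgeR adjusted p = 0.195). In replicate 3 it was at 815 CPM in the one labelled scrambled and at 295 CPM in the one labelled AEBP1 siRNA. ARL6IP1, which shapes the endoplasmic reticulum, was at 400 and 410 CPM against 166 and 170 CPM (adjusted p = 0.208), and in replicate 3 at 152 CPM labelled scrambled and 402 CPM labelled AEBP1 siRNA. IL1B, an inflammatory cytokine, was at 470 and 426 CPM against 237 and 222 CPM (adjusted p = 0.286), and in replicate 3 at 185 CPM labelled scrambled and 462 CPM labelled AEBP1 siRNA. CDCA8, a subunit of the chromosomal passenger complex of mitosis, had a log2 fold change of -1.05 (adjusted p = 0.254). All 4 carry in the 3′ UTR at least 1 of the heptamers GGGAACA and TGGGAAC treated below. So do 13 of the 15 lower genes and 2 of the 9 higher genes with a searched 3′ UTR among 25 genes with a small p. The 25 were taken in order of p after a filter on mean level, and leave out AL355312.5, the gene called in this comparison. The heptamers were picked for their low effects in this same comparison, so these shares are no independent evidence. The lower values of such genes may come from the siRNA sequence and not from AEBP1, while TPM4, with a site, was higher. SENP3-EIF4A1, of the same 25, had a log2 fold change of 4.14 and no searched 3′ UTR.

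In the same comparison NF-kB and inflammatory genes had a median log2 fold change of -0.255 over 36 members (camera adjusted p = 9.12e-08) and the type I interferon response of -0.387 over 34 (camera adjusted p = 9.12e-08). Genes of the G2 and M phases, matrix glycoproteins and collagens had medians of -0.143, -0.174 and -0.124 (camera adjusted p = 0.0026, 0.011 and 0.0416). With an estimated correlation the adjusted p was 0.794 for 4 of these lists and 0.807 for matrix glycoproteins. In replicate 3 the lists went the other way, by medians relative to the mean of the 6 libraries. In scrambled 3 and AEBP1 siRNA 3, NF-kB genes were at -0.249 and 0.18 and interferon genes at -0.138 and 0.073. Genes of the G2 and M phases were at -0.0726 and 0.0679, matrix glycoproteins at 0.0499 and 0.103, and collagens at -0.0106 and 0.101. The matrix calls depend on the library labelled AEBP1 siRNA 1: with it left out as well, matrix glycoproteins were at -0.0221 (camera adjusted p = 0.506) and collagens were no longer called.

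AEBP1 went against the label in replicate 3 of both groups, and a sequence scan gave a test that leaves AEBP1 aside. In AEBP1 siRNA 1 and 2 against scrambled 1 and 2, GGGAACA, in the 3′ UTR of 1453 genes, had the lowest effect relative to its SE of 16192 heptamers, at -0.0958 in log2 (SE 0.00591), and in AEBP1 siRNA 3 minus scrambled 3 the same heptamer had the highest, at 0.0978 (SE 0.0059). A failed knockdown in AEBP1 siRNA 3 alone is argued against by scrambled 3, with the heptamer picked and read in separate libraries. Picked in AEBP1 siRNA 1 and 2 against scrambled 2, GGGAACA again came first, and its effect in scrambled 3 minus scrambled 1 was -0.099 (SE 0.00666). With scrambled 1 and 2 exchanged it was -0.0964 (SE 0.00572). Variation of AEBP1 without other genes is argued against as well. Of 573 genes with a mean of at least 5 CPM and an unadjusted p under 0.05 in replicates 1 and 2, 93.7% had the opposite sign in replicate 3 (95% exact binomial interval 91.4% to 95.6%, across genes), against 57.5% of all 11586 genes with such a mean. A difference between cultures or batches that moves AEBP1 along with many genes, with no part of the siRNA, would give the same signs and stays open. A candidate explanation is that the libraries of replicate 3 carry each other's label. SENP3-EIF4A1, RAB4B-EGLN2 and NEDD8-MDP1 follow the labels in all 6 libraries, which a swap of samples alone leaves unexplained. They were picked for the smallest p between the labelled groups, so their agreement with the labels is no independent evidence against a swap. Other read-through genes with an unadjusted edgeR p under 0.05 were NME1-NME2, NDUFC2-KCTD14, PMF1-BGLAP, RBM14-RBM4 and HNRNPUL2-BSCL2, whose labelled groups did not overlap. SPECC1L-ADORA2A, also under 0.05, overlapped and varied widely, at 2.38 CPM ± 3.58 (SD) in the libraries labelled AEBP1 siRNA. A small p favours groups that do not overlap, so these genes are no independent evidence either.

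The heptamers may come from the siRNA itself, since a guide strand can repress transcripts that match its seed. TGGGAAC, shifted by 1 base, ranked 2 from the lowest (-0.0939, SE 0.00594). The AEBP1 transcript, as the target, would then hold the seed match, and it held 3 sites of TGGGAAC and none of GGGAACA. In GRCh38 the 3 sites lie on chromosome 7 at 44110921 to 44110927 in exon 13, 44111957 to 44111963 in exon 16 and 44112153 to 44112159 in exon 17, all in coding sequence. Of 2808 expressed genes with a transcript length within 20% of 4081 nt, 27.6% had at least 1 such site and 0.605% at least 3. The highest heptamers were TCGGAGA (0.104, SE 0.0134) and CGGAGAA (0.0837, SE 0.0124), again shifted by 1 base, and the scrambled siRNA is a possible source. The AEBP1 transcript held 1 site of each of these as well, as 13.0% and 16.7% of the genes of like length held at least 1, so holding a site is not specific to the guide against AEBP1. The siRNA sequences are not given in the sources used here, so seed pairing of either guide stays open. In that comparison, among genes with a mean of at least 5 CPM, 188 of 312 with an unadjusted p under 0.05 and a lower value (60.3%) carried GGGAACA or TGGGAAC in a searched 3′ UTR, against 1962 of 10391 with a larger p (18.9%). The heptamers were picked in these libraries, so that share is no independent evidence. Such genes could be low through seed pairing and not through loss of AEBP1.

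The library labelled AEBP1 siRNA 1 stood apart, with a spread of its genes around the median of the others of 0.372 in log2, where the other 5 lay between 0.118 and 0.164. Lower depth is argued against: with all libraries thinned to 34433510 counts, the highest spread of the others was 0.445 times that of AEBP1 siRNA 1. Its differences correlated with transcript length at a Spearman rho of -0.693 across genes, and removing the trends on length and GC content lowered its spread to 0.221. That was still 1.54 times the highest of the others, so length and GC bias may be a part of the difference but not the whole. The calls of ribosomal proteins, the respiratory chain and matrix glycoproteins were lost without this library, and the list tests were not adjusted for length or GC content. Whether these trends gave those calls was not tested. A difference between the cultures stays open and was not tested.

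SENP3-EIF4A1 was the called gene, and reads shared between overlapping genes are a candidate explanation. The read-through gene gained 218 CPM in the libraries labelled AEBP1 siRNA, SENP3 and EIF4A1 differed by -26.5 and -133 CPM, and the summed locus gained 58.2 CPM (SE 55.9). Most of the summed gain came from AEBP1 siRNA 1. The sum was 729, 579 and 550 CPM in AEBP1 siRNA 1, 2 and 3, and 557, 554 and 573 CPM in scrambled 1, 2 and 3. Whether the authors' transcript assembly or counting differed between the groups is not given in the sources used here. A change in read-through transcription was not tested.

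The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. As many genes as in the labelled groups came from 3 of the 10 splits, the labelled one included, with 1 gene for the labels and 140 for the highest other. For genes changed at least 2-fold it was 3 of 10, with 1 and 34, and for gene lists 7 of 10, with 4 and 7. The split with 140 genes, of scrambled 1 and 2 and AEBP1 siRNA 3 from the rest, points to a structure of the samples that the labels do not follow.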
